A study of Mus musculus with 3 samples.

How the data were processed

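The series holds 3 two-colour arrays of mouse RNA. Per the labels, every array carried a commercial spleen total RNA labelled with Cyanine-3 (green) and a commercial liver total RNA labelled with Cyanine-5 (red). Per the labels, labelled cRNA was made from both RNAs with 1 round of amplification, and the series title names the arrays as oligonucleotide arrays. The labels give the same catalogue product for each tissue on all 3 arrays and do not say whether the lots, the amplifications or only the hybridizations were repeated. They do not say how many mice or which sex, age or strain stood behind each RNA. The 3 arrays were therefore treated as repeats of 1 pair of RNAs. Each gene's SD and p-value below measure the spread between arrays, which may be technical, and not the spread between animals. The p-values of the list and family tests set genes against other genes, and those of Fisher's exact test count probes. None of them measures the spread between animals, and SDs over genes are named as such.

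The deposited table gives, for 16281 probes, 1 log2 ratio of the channels per array. The log base is not stated in the sources used here. It was taken from the values: the highest value on every array is 6.64, the log2 of exactly 100, as from a ratio that was limited to 100-fold before the table was made. Each deposited log2 column has a median of 0 with its values of exactly 0 included. Without them the medians were 0.02, 0.04 and 0.01 on arrays 1, 2 and 3. The background correction, the dye normalization and any filtering by the authors are not given in the sources used here, and neither channel's intensity was used here. Depth has no meaning for these arrays, and their number limits the precision.

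The deposited log2 table lists an exact 0 for 1414 probes on array 1, 1098 on array 2 and 1137 on array 3. These include probes of abundant transcripts such as albumin and transthyretin, so an exact 0 was taken as no measurement. With these left out, 14122 probes had a value on all 3 arrays. The direction of the deposited ratio is not stated. It was checked with 8 liver and 8 spleen genes fixed before the data were examined and kept out of the list tests. The rule was that the medians of the 2 sets lie on opposite sides of 0 on every array.

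Probes were named from the platform annotation, and each symbol was checked through its Entrez number in a RefSeq gene table. Of the 16281 probes, 13738 had 1 gene symbol, 52 had several and 2491 had none. The Entrez number was found for 13694 probes and no symbol changed. For the other 44 the symbol of the platform annotation was kept. Probes with several symbols or none were left out of the main tests. Genome positions are not given, because no genome build is named for the probes. Log ratios of different probes of a gene were averaged on each array, over probes measured on all 3 arrays. This left 9803 genes.

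Each gene's log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3, using an intercept-only fit, moderated variances (3.38 prior degrees of freedom) and two-sided p-values with Benjamini-Hochberg adjustment. A gene was past the test at an adjusted p under 0.05. Because repeat arrays of 1 pair of RNAs make even small differences pass, a 2-fold limit was also set. Before the data were examined, 34 gene lists were fixed, 2 of them the direction sets. The other 32 were tested with limma's camera, which asks whether a list's genes lie further to one side than the other genes, with a preset correlation between genes of 0.01 and adjustment over the 32 lists. Camera was also run with the correlation estimated from the 3 arrays, which leaves 2 residual degrees of freedom, and fry was run as a test of each list's own mean. A list needed at least 4 measured members, and all 32 had them.

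The genes named in the text were chosen by a rule fixed before the data were examined. It took the 10 genes with the largest mean ratio in each direction that passed the test with the same sign on all arrays. From each list it took the 3 largest members past the test, and the largest member past it in the opposite direction. The direction genes and sex-linked genes could all be named. Members that did not pass are named with values only. The text names most but not all of the genes this rule took. Klkb1, F11, Plg, Pklr, Hnf4a, Pax5, Blk, Ms4a1, Hba-a1, Gapdh, Ckm, Adipoq, Fabp4, Retn, Cidec, Ucp1 and Hsd3b5 were chosen after their values were seen. So were the gene family examples and the probes listed at 0.

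The gene and list tests were tested on simulated data over 5 runs. Genes were drawn independently, each with a spread drawn with replacement from those of the 9803 genes. The gene test called 25.3% of the genes changed by 0.5 on the log2 scale, 68.7% of those changed by 1 and 90.0% of those changed by 2. Of its 651 calls, 2.15% were false. Over the 5 runs, 435, 335 and 330 genes were changed by 0.5, 1 and 2, and 47915 were unchanged. In the real data 52.8% of the genes passed, which eases the adjusted threshold, so these shares need not hold there. Camera called a list of 20 genes shifted by 0.5 in 5 of 5 runs and 1 of 95 unshifted lists. Because the simulated genes were independent, this does not check the preset correlation. Most of them had a true ratio of 0, against an SD over genes of 0.892 to 1.01 on the real arrays. A shift of 0.5 may therefore be harder to find there. Alternatives tried were centring and scaling the arrays, leaving out each array, other variance models and thresholds, other fold limits, probes in place of genes, other set tests, and keeping the zeros as values. Numbers were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.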

Results

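Gene expression in mouse liver was compared with that in mouse spleen on 3 two-colour oligonucleotide arrays, each with the spleen RNA in the green dye and the liver RNA in the red dye. The design answers which transcripts differ in level between these 2 RNAs. It holds no array with the dyes exchanged, so a probe's dye bias and its tissue difference cannot be told apart. All values are log2 ratios, given as the mean ± SD over n = 3 arrays, and folds are computed from these means.

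The ratio was read as liver over spleen, which is likely but not stated in the labels. The basis was a set of genes kept for this purpose. Ahsg, a liver plasma glycoprotein, read 4.04, 3.45 and 3.80 on arrays 1, 2 and 3. Albumin (Alb) read 6.16 on array 2 and was listed at 0 on the others, and Serpina1b, an antiprotease of liver, read 4.62 on array 2. The median of the liver set was 4.04, 4.62 and 3.80 on the 3 arrays, resting on Ahsg alone on arrays 1 and 3. The median of 7 spleen genes was -1.38, -1.60 and -1.16. Among them the B-cell receptor chain Cd79b averaged -1.38 ± 0.22, the invariant chain Cd74 -1.82 ± 0.04 and the leukocyte phosphatase Ptprc -2.15 ± 0.21. The T-cell receptor chain Cd3e was at 0.13 ± 0.09 and did not pass the test (adjusted p = 0.217). Of the Ptprc probes measured on all arrays, 1 averaged -4.33 and the other 0.03.

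The arrays gave closely similar ratios. Across the 9803 genes, Pearson's r was 0.954 between arrays 1 and 2, 0.946 between arrays 1 and 3, and 0.941 between arrays 2 and 3. Genes are not independent replicates, so these values describe the arrays only. A gene's SD over the 3 arrays had a median of 0.15, against a median absolute mean log2 ratio of 0.31. Array 3 had a narrower range of ratios, with an SD over genes of 0.892 against 0.997 on array 1 and 1.01 on array 2.

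**Figure D1:**
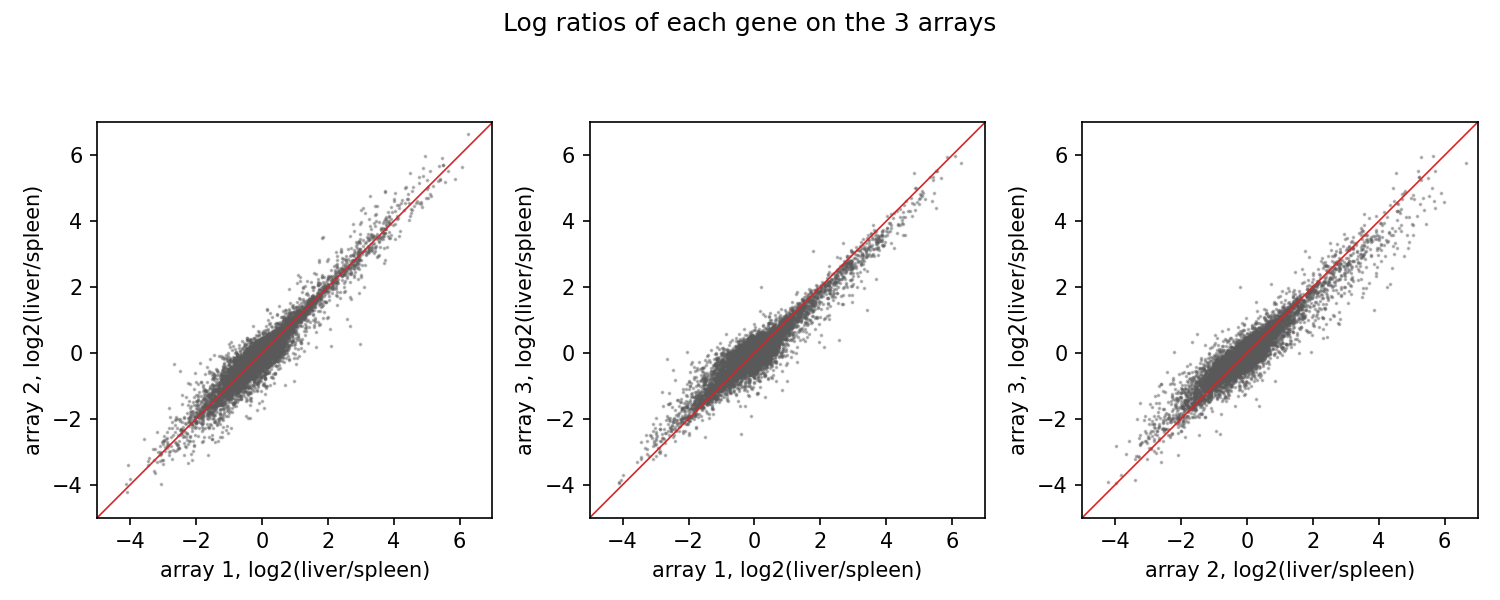
Log2 ratio (liver over spleen) of each of the 9803 genes on each pair of arrays, with the line of equal values in red. Points follow the line with Pearson's r of 0.954, 0.946 and 0.941 across genes, and array 3 gives smaller ratios at both ends.

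Of the 9803 genes, 5174 (52.8%) passed limma's test, 2484 of them higher in liver and 2690 higher in spleen. At 2-fold or more, 903 genes were higher in liver and 823 higher in spleen. The large differences lay mostly on the liver side. At 4-fold or more there were 418 genes higher in liver and 142 higher in spleen, and at 16-fold or more there were 61 and 2. Another 4629 genes did not pass the test. The counts of list and family members past the test given below are to be read against the 52.8% of all genes. A count near that share does not by itself set a list apart.

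Toward liver, Slco1b2, an uptake carrier for organic anions in hepatocytes, had the highest mean of the 9803 genes at 6.23 ± 0.44, a 74.9-fold ratio. On array 2 it stood at the table's limit of 6.64, so the mean is a lower bound. Mannose-binding lectin (Mbl2) followed at 5.90 ± 0.22 and prothrombin (F2) at 5.70 ± 0.36, the latter from 1 probe while another probe of F2 was listed at 0 on every array. The glucuronosyltransferase Ugt1a6a was at 5.58 ± 0.12, Sipa1l3 at 5.50 ± 0.17 and Pbld2 at 5.43 ± 0.20. Serum amyloid P (Apcs) was at 5.41 ± 0.52 and the iodotyrosine deiodinase Iyd at 5.33 ± 0.09. The secreted binding protein Igfbp1 and the lysine-degrading enzyme Aass were both at 5.31, with SDs of 0.10 and 0.06. Their adjusted p-values (limma) lay between 1.06e-05 and 2.28e-05. Genes with near-identical relatives, among them the Ugt1a, Cyp and Igkv families, may share signal between probes, and this was not resolved here.

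Toward spleen, Spib, a transcription factor of lymphocytes, averaged -4.08 ± 0.15, a 16.9-fold ratio, and the B-cell kinase Btk -4.01 ± 0.10. Trim59 was at -3.83 ± 0.15 and cochlin (Coch) at -3.77 ± 0.33. The adhesion molecule Vcam1 was at -3.35 ± 0.12 and the condensin subunit Smc4 at -3.33 ± 0.30. The immunoglobulin kappa segment Igkv4-68 averaged -3.29 ± 0.60 and the membrane protein Ms4a4c -3.29 ± 0.15. Gm8989 followed at -3.21 ± 0.10 and the acetyl-CoA synthetase Acss1 at -3.17 ± 0.46. Their adjusted p-values (limma) lay between 1.06e-05 and 0.000153. In both directions these top genes had 1 measured probe each. Genes with more probes were averaged over them, which can lower their rank where the probes differ, as for Ptprc above. Genes without a probe measured on all 3 arrays were not ranked.

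**Figure D2:**
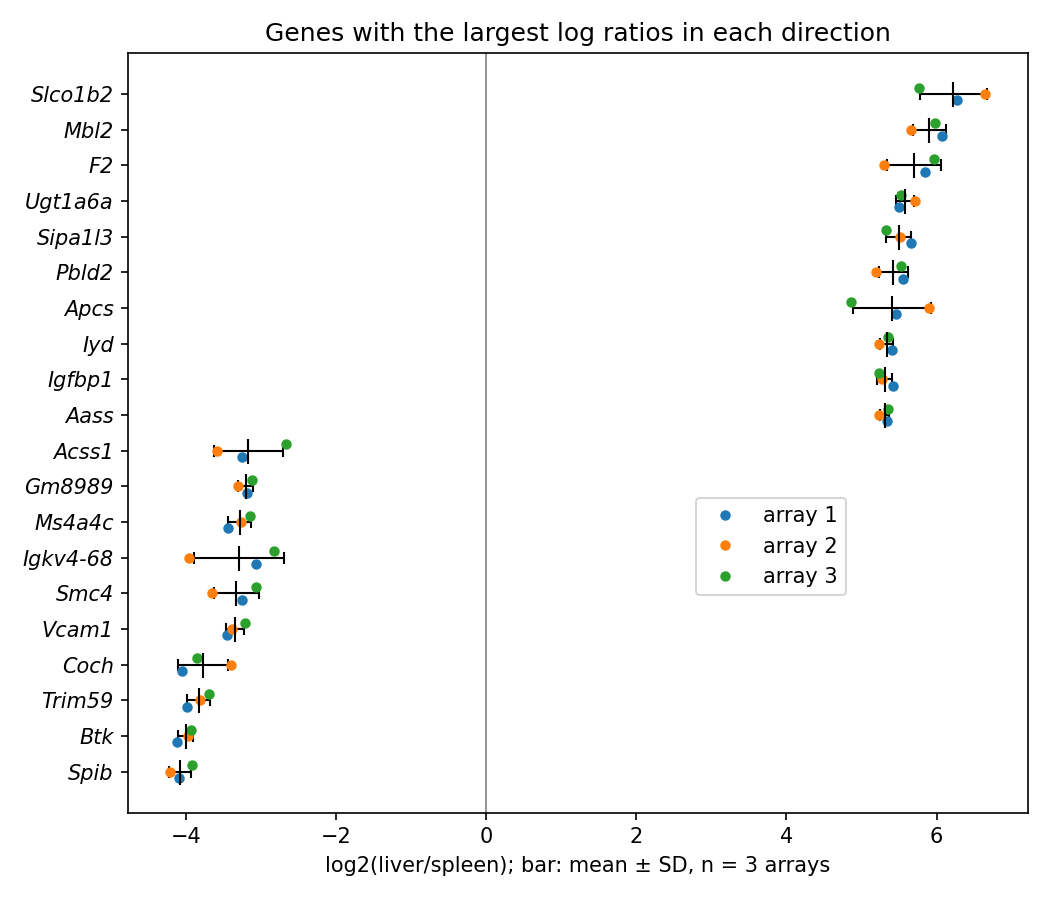
Log2 ratio (liver over spleen) of the 10 genes with the largest mean ratio in each direction. Coloured points are the 3 arrays and the bar is the mean ± SD, and the lowest point of the liver genes is 4.86, the value of Apcs on array 3. Each gene shown rests on 1 measured probe.

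Secreted liver proteins were higher in the liver RNA as groups. Of 24 measured genes of complement and coagulation, 22 passed the test toward liver and none toward spleen, also with p-values adjusted over the list alone. Their median was 2.57. Without array 2, 1 member passed toward spleen. Besides Mbl2 and F2, the terminal complement component C9 averaged 4.40 ± 0.74. Klkb1 at -0.24 ± 0.54 did not pass, nor did F11, which read -0.04, -0.23 and 0.26 on the 3 arrays. Plasminogen (Plg) averaged 0.58 on the probe measured on all arrays, while another of its probes, listed at 0 on array 1, read 5.85 and 4.89 on arrays 2 and 3. Of 31 plasma carriers and apolipoproteins, 29 passed toward liver and none toward spleen, again the same count adjusted over the list alone, with a median of 3.36. The acute-phase protein Orm1 averaged 4.62 ± 0.78 and the inter-alpha-trypsin inhibitor chain Itih1 4.47 ± 0.10. Apoa1, Apoa2, Apoc1, Apoh, Rbp4 and transthyretin (Ttr) were listed at 0 on every array and have no ratio. Camera placed both lists toward liver, with adjusted p-values of 3.16e-10 and 3.53e-14 and an adjusted p = 0.254 with an estimated correlation for each.

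Enzymes of liver metabolism followed the same direction. All 17 measured genes of the urea cycle and amino acid catabolism passed toward liver, with a median of 3.25. Ornithine transcarbamylase (Otc) averaged 4.97 ± 0.27 and arginase (Arg1) 4.86 ± 0.17. All 20 genes of fatty acid oxidation and ketogenesis passed toward liver, with a median of 2.76. Among them the peroxisomal enzyme Ehhadh was at 4.94 ± 0.15, the fatty acid transporter Slc27a2 at 4.86 ± 0.51 and the fatty acid binding protein Fabp1 at 4.53 ± 0.40. Of 9 genes of glucose and glycogen metabolism, 8 passed toward liver, led by the gluconeogenic enzymes Pck1 at 5.22 ± 0.55 and Fbp1 at 4.32 ± 0.18 and the glucose-6-phosphate carrier Slc37a4 at 3.09 ± 0.10. Pyruvate kinase Pklr was at 0.19 ± 0.56 and did not pass. Of 13 genes of sterol and fatty acid synthesis, 12 passed toward liver, 13 when adjusted over the list alone. Sc5d was at 2.90 ± 0.28, Fads1 at 2.85 ± 0.26 and squalene epoxidase (Sqle) at 2.41 ± 0.13. The counts of the other 3 lists were the same adjusted over the list alone. Camera gave adjusted p-values of 1.59e-10, 5.97e-12, 5.15e-06 and 1.29e-06 for the 4 lists in this order. With an estimated correlation the adjusted p = 0.254 for the first 3 and adjusted p = 0.327 for sterol and fatty acid synthesis.

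Of 31 measured cytochromes P450, the oxygenases of drug and steroid metabolism, 28 passed toward liver and 1 toward spleen. Adjusted over the list alone, 30 passed toward liver and 1 toward spleen. Cyp2j5 averaged 5.17 ± 0.72, Cyp3a11 4.94 ± 0.48 and Cyp3a25 4.93 ± 0.37. Cyp1b1 was the member higher in spleen, at -1.89 ± 0.84. Among 26 genes of conjugation and other detoxification, 25 passed toward liver and none toward spleen, the same count adjusted over the list alone. The alcohol dehydrogenase Adh4 was at 5.20 ± 0.71, the glucuronosyltransferase Ugt2b5 at 4.93 ± 0.36 and the carboxylesterase Ces1g at 4.66 ± 0.16. Of 16 genes of bile acid synthesis and hepatic transport, 15 passed toward liver and 1 toward spleen, the same adjusted over the list alone, with a median of 3.49. The bile acid CoA ligase Slc27a5 was at 4.92 ± 0.19 and the conjugating enzyme Baat at 4.79 ± 0.18. The member toward spleen was the bile acid carrier Slc10a1, at -0.36 ± 0.13 on the probe measured on all arrays and not past the test without array 1, where it averaged -0.29. Another Slc10a1 probe, listed at 0 on array 2, read 4.77 and 4.19 on arrays 1 and 3. The adjusted p-values by camera for the 3 lists were 1.09e-12, 2.34e-12 and 6.61e-08, and the adjusted p = 0.254 with an estimated correlation for each.

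Liver transcription factors were higher in liver, with a median of 1.98. Of 14 measured, 13 passed toward liver, also adjusted over the list alone. The nuclear receptors Nr5a2, Ppara and Nr1h4 averaged 3.59 ± 0.33, 3.15 ± 1.12 and 2.92 ± 0.20. Hnf4a, at 0.04 ± 0.93, did not pass and read 0.99, -0.02 and -0.86 on the 3 arrays. Oxidative phosphorylation genes passed toward liver in 38 of 39 cases, the same adjusted over the list alone, with a median of 1.13. The complex I subunit genes Ndufa4 and Ndufs3 were at 2.05 ± 0.04 and 1.69 ± 0.08, and the succinate dehydrogenase gene Sdhb at 1.98 ± 0.03. Of 27 proteasome subunit genes, 21 passed toward liver and 1 toward spleen, and adjusted over the list alone 21 and 2. The count toward spleen was 0 without any 1 of the arrays, and 2 with arrays centred. Their median was 0.49, and Psmb6, Psmb2 and Psmb7 were at 1.18 ± 0.11, 1.06 ± 0.12 and 0.84 ± 0.06. By camera the adjusted p-values were 2.22e-06, 6.79e-14 and 1.12e-05, and the adjusted p = 0.254 with an estimated correlation for each of the 3.

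Lymphocyte genes were higher in the spleen RNA. Of 23 measured B-cell genes, 16 passed toward spleen and 1 toward liver, the same adjusted over the list alone, with a median of -0.86. Besides Spib and Btk, the surface receptor Cd72 averaged -2.77 ± 0.19. Pax5 at -0.18 ± 0.28 and Blk at -0.04 ± 0.47 did not pass. Ms4a1, the CD20 antigen, was at 0.05 ± 0.29 on the probe measured on all arrays, while another of its probes read -4.51 on array 2 and was listed at 0 on the others. Of 36 genes of T and NK cells, 23 passed toward spleen and 1 toward liver, and adjusted over the list alone 24 and 1. In the B-cell list, the count toward liver was 0 without array 1 or array 3. The interleukin receptor Il7r was at -2.82 ± 0.12, Ms4a4b at -2.77 ± 0.10 and the signalling adaptor Sh2d1a at -2.17 ± 0.26, while the kinase Zap70 was at 0.54 ± 0.04. The median of the T and NK list was -0.79, and -0.45 over its 14 genes with a single measured probe (adjusted p = 0.00396). Of 21 genes of MHC class II and dendritic cells, 13 passed toward spleen and 3 toward liver, and adjusted over the list alone 14 and 3. The count toward liver was 1 without any 1 of the arrays. The activation marker Cd83 averaged -2.75 ± 0.27, the transcription factor Irf8 -2.30 ± 0.32 and the class II chain H2-Ea -2.16 ± 0.22. Camera's adjusted p-values were 2.08e-05, 2.28e-07 and 0.00115 for the 3 lists. With an estimated correlation these were adjusted p = 0.301, adjusted p = 0.254 and adjusted p = 0.254.

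Erythroid and dividing-cell genes were also higher in spleen. Of 23 erythroid genes, 18 passed toward spleen and 2 toward liver, the same adjusted over the list alone, with a median of -1.40. The erythroid transcription factor Klf1 averaged -3.04 ± 0.24, hemogen (Hemgn) -2.94 ± 0.18 and carbonic anhydrase Car2 -2.57 ± 0.19. The erythroid count toward liver was 1 without any 1 of the arrays or with arrays centred. Rhag, a blood-group glycoprotein of red cells, went the other way at 1.66 ± 0.26. Probes of the globin genes Hba-a1 and Hbb-b2 were listed at 0 on every array, and the measured Hba-a1 probe was at -0.02 ± 0.26. Of 49 cell cycle genes, 39 passed toward spleen and 1 toward liver, and adjusted over the list alone 40 and 1. Without array 1, 0 passed toward liver. The replication helicase subunit Mcm4 averaged -2.88 ± 0.13, cyclin A (Ccna2) -2.80 ± 0.22 and the proliferation marker Mki67 -2.60 ± 0.27. By camera the adjusted p-values were 8.40e-06 and 1.21e-10, and the adjusted p = 0.254 with an estimated correlation for both. The 5 measured heme synthesis genes were mixed, with 2 toward spleen and 1 toward liver. Adjusted over the list alone, 3 passed toward spleen and 1 toward liver. Uros averaged -0.62 ± 0.04, Ppox -0.62 ± 0.20 and Alad 0.45 ± 0.09. Alas1, also of this list, is not among the 5. A probe of it read 4.14, toward liver, on array 2 and was listed at 0 on arrays 1 and 3. The list did not pass camera (adjusted p = 0.382).

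Myeloid and platelet genes leaned to spleen, with exceptions. Of 28 macrophage genes, 22 passed toward spleen and 3 toward liver, the same adjusted over the list alone. Lysozyme (Lyz2) averaged -2.66 ± 0.38 and the scavenger receptor Marco -2.05 ± 0.26. Clec4f, a lectin of Kupffer cells, the macrophages of liver, was at 1.62 ± 0.17, with 1 probe at 3.18 and the other at 0.05. Of 25 granulocyte genes, 14 passed toward spleen and 2 toward liver, the same adjusted over the list alone. S100a9, a calcium-binding protein of neutrophils, was 8.03-fold higher in spleen, with an SD of 0.45 on the log2 scale. The pair toward liver were haptoglobin (Hp), also a plasma protein made in liver, at 3.62 ± 0.11, and Ly6g at 2.61 ± 0.26. Of 15 platelet and megakaryocyte genes, 8 passed toward spleen and none toward liver, the same adjusted over the list alone. Plek averaged -2.53 ± 0.51 and the integrin Itga2b -1.52 ± 0.06. Platelet factor 4 (Pf4) averaged -1.39 ± 0.20, with 1 probe at -3.06 and the other at 0.28. Camera's adjusted p-values were 1.12e-05, 0.00155 and 0.00596. With an estimated correlation these were adjusted p = 0.254, adjusted p = 0.351 and adjusted p = 0.280. Among genes with a single measured probe, neither granulocytes nor platelets passed camera. The granulocyte mean went from -0.49 over 25 genes to 0.02 over 11 (adjusted p = 0.288), while the platelet mean was -0.68 over 15 genes and -0.75 over 6 (adjusted p = 0.0881). The median of the 11 granulocyte genes was -0.22, and Hp and Ly6g are among them.

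The 3 lists of stromal, endothelial and biliary genes held members past the test in both directions. Of 17 genes of lymphoid stroma and chemokines, 9 passed toward spleen and 2 toward liver, and adjusted over the list alone 10 and 2. The complement receptor Cr2, which is also in the B-cell list, averaged -1.85 ± 0.29. The B-cell chemokine Cxcl13 averaged -1.62 ± 0.20, from probes at -3.26 and 0.02. The addressin Madcam1 was at 2.74 ± 0.26. Of 24 genes of smooth muscle and extracellular matrix, 11 passed toward spleen and 3 toward liver, the same adjusted over the list alone. The contractile-cell genes Tagln and Tpm2 averaged -2.35 ± 0.45 and -1.82 ± 0.21, and fibronectin (Fn1) 3.42 ± 0.16. Of 12 genes of hepatic stellate, endothelial and biliary cells, 7 passed toward liver and 1 toward spleen, and adjusted over the list alone 7 and 2. The count toward spleen was 0 without any 1 of the arrays, and 2 with arrays centred. The collectin Colec11 averaged 2.55 ± 0.22, Ecm1 1.20 ± 0.37 and reelin (Reln) 0.94 ± 0.16. Camera's adjusted p-values were 0.0128, 0.245 and 0.0488 for the 3 lists, and the third did not pass without array 2 (adjusted p = 0.0692) or array 3 (adjusted p = 0.0583). With an estimated correlation these were adjusted p = 0.254, adjusted p = 0.646 and adjusted p = 0.254. Among genes with a single measured probe the first list did not pass (adjusted p = 0.124). Its mean was -0.37 over 17 genes and -0.21 over the 12 with a single probe, whose median was -0.43. The third list did not pass either (adjusted p = 0.231), with a mean of 0.55 over 12 genes and 0.63 over 7, and medians of 0.50 and 0.18.

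Ribosomal protein genes were higher in spleen. Of the 70 on the array only 38 had a value on all 3 arrays, and 27 of these passed toward spleen and 1 toward liver, with a median of -0.70. Adjusted over the list alone, 28 passed toward spleen and 1 toward liver. With the zeros kept as values, the median over all 70 was -0.22 (camera adjusted p = 8.71e-05). Rpl22l1 averaged -1.44 ± 0.09, Rpl36a -1.43 ± 0.03 and Rps27l 1.47 ± 0.02. Of 19 interferon-response genes, 13 passed toward spleen and none toward liver, and adjusted over the list alone 14 and none. Their median was -0.50. The antiviral gene Rsad2 averaged -1.96 ± 0.16 and the GTPase Gbp3 -0.85 ± 0.15. Of 22 immediate early and heat shock genes, 10 passed toward spleen and 4 toward liver, the same adjusted over the list alone. The count toward liver was 1 without array 1 or array 2 and 2 without array 3. The transcription factor Klf2 averaged -1.99 ± 0.15, the chaperone Hspa1a -1.48 ± 0.24 and the phosphatase Dusp1 1.51 ± 0.11. With camera these lists had adjusted p-values of 7.74e-07, 0.000366 and 0.0263, and the adjusted p = 0.254 with an estimated correlation for each. Of 13 housekeeping genes, 4 passed toward liver and 3 toward spleen, the same adjusted over the list alone. Without array 1, 2 passed toward liver. The tubulin gene Tuba1b averaged -2.27 ± 0.15 and the glycolytic gene Pgk1 1.35 ± 0.10. Camera gave an adjusted p = 0.861, with the list's median at 0.01 and its mean at -0.07. With each probe tested by itself the list passed toward liver, over 38 probes of which 23 were those of Gapdh (median 0.37, adjusted p = 0.00199).

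**Figure D3:**
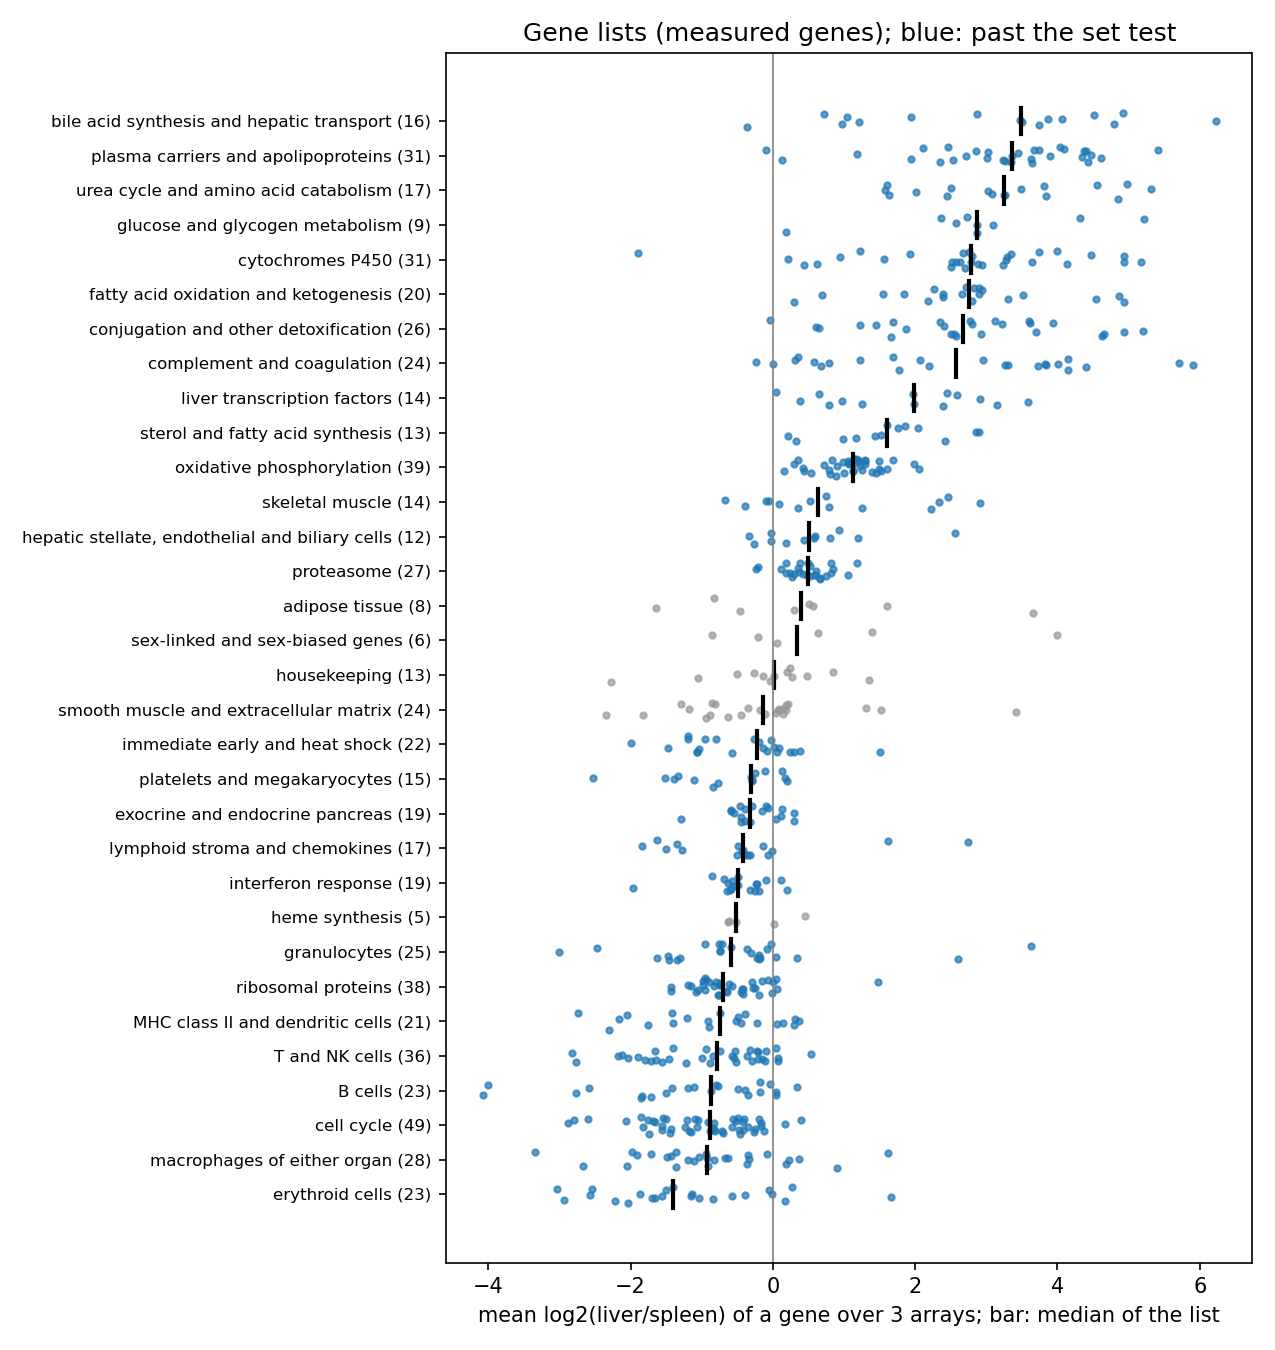
Mean log2 ratio (liver over spleen, 3 arrays) of each measured gene in the 32 lists, with the number of measured genes in brackets and the list median as a bar. Lists past camera's test are blue, and medians run from -1.40 for erythroid genes to 3.49 for bile acid synthesis and hepatic transport.

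Markers of other tissues were measured as well. Of 19 pancreas genes, 10 passed toward spleen and 2 toward liver, and adjusted over the list alone 11 and 2. The count toward liver was 0 without any 1 of the arrays, and that toward spleen was 7 without array 1. The list's median was -0.32. Spink1, a trypsin inhibitor, had the largest at -1.29 ± 0.08, and the lipase-related genes Pnliprp1 and Pnliprp2 were both at -0.59, with SDs of 0.07 and 0.11. Of 14 skeletal muscle genes, 9 passed toward liver and 2 toward spleen, the same adjusted over the list alone. Skeletal actin (Acta1) averaged 2.91 ± 0.20 and the myosin heavy chains Myh2 and Myh1 2.46 ± 0.42 and 2.34 ± 0.12. The fast myosin Myh4 was at -0.68 ± 0.36. It did not pass the test without array 1 (mean -0.59) or array 2 (mean -0.56), and without array 2 the list's count toward spleen was 0. Of 8 adipose genes, 5 passed toward liver and 3 toward spleen, the same adjusted over the list alone. Carbonic anhydrase Car3 was at 3.65 ± 0.74, Thrsp at 1.60 ± 0.16 (probes at -0.14 and 3.34) and lipoprotein lipase (Lpl) at -1.65 ± 0.08. Thrsp is also in the list of sterol and fatty acid synthesis. The other members past the test toward spleen were Adipoq at -0.83 ± 0.16 and Fabp4 at -0.46 ± 0.17. Those toward liver were Retn at 0.56 ± 0.04, Cidec at 0.50 ± 0.14 and Ucp1 at 0.29 ± 0.15. Camera's adjusted p-values were 0.0263, 0.0119 and 0.473. These became adjusted p = 0.366, adjusted p = 0.254 and adjusted p = 0.577 with an estimated correlation. Among genes with a single measured probe, the muscle list did not pass (adjusted p = 0.0584), with a mean of 0.87 over 12 genes against 0.89 over 14.

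Of the measured sex-linked genes, Xist and Kdm5d passed the test, in opposite directions. Xist, expressed from the inactive X chromosome, averaged 1.40 ± 0.10 toward liver, with 1 probe at 1.84 and the other at 0.96. The Y-linked gene Kdm5d was at -0.85 ± 0.34, toward spleen. The Y-linked genes Eif2s3y at -0.21 ± 0.07 (adjusted p = 0.0634, probes at -0.55 and 0.12) and Uty at 0.05 ± 0.11 (adjusted p = 0.615) did not pass. Cyp2b9, a cytochrome P450 that differs between the sexes in mouse liver, passed the test toward liver and read 4.15, 4.51 and 3.34 on the 3 arrays. Hsd3b5, of the same list, also passed toward liver, at 0.63 ± 0.11. Both were compared with spleen only, so these ratios do not tell the sex behind the liver RNA. Of the 6 measured genes of the sex-linked and sex-biased list, 3 passed toward liver and 1 toward spleen, and adjusted over the list alone 3 and 2. The list did not pass camera (adjusted p = 0.301).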

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

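The tests in this part were chosen after the results were seen, except that on the receptor probes, whose prediction was written before its result.

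Many probes were listed at exactly 0, and some of them carried large ratios on another array. Of 1321 named probes at 0 on 1 or 2 arrays, 28 had a log2 ratio of at least 4 either way on another array. Among them were Elovl2 at 6.64 on arrays 2 and 3, Fabp1 at 6.13 and 6.15 on arrays 1 and 2, Kng1 at 5.01 and 5.15 on the same arrays, and Ms4a1 at -4.51 on array 2. A rule that blanked only dim spots does not account for this. Probes of ribosomal proteins, which are abundant in every tissue, were at 0 on at least 1 array in 33 of 71 cases (46.5%), against 10.6% of the other named probes (odds ratio 7.34, 95% interval 4.44 to 12.1, two-sided Fisher's exact test, adjusted over 5 classes p = 1.28e-13). A rule that blanked only bright spots does not account for it either: probes of olfactory and vomeronasal receptors, which liver and spleen are not known to express, were at 0 in 17.7% of cases (odds ratio 1.80, 95% interval 1.08 to 2.88, adjusted p = 0.0311). Blanking of both very bright and very dim spots stays open, and no biological explanation was tested.

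Probes with no gene symbol or several were outside the comparisons of genes. Of 1863 measured on all arrays, 938 passed the test and 345 did so at 2-fold or more, 163 toward liver and 182 toward spleen, with means from -4.44 to 4.97.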

How the results depend on the processing

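The zeros kept as values, the added unnamed probes and the restriction to genes with 1 measured probe were chosen after seeing the data. Of 47 recomputed counts and spreads, 41 stayed within 1.5 times the value reported, or within its spread. The exceptions were these. A test per gene with no moderation called 2660 genes in place of 5174, and the estimated correlation left 0 of 32 lists past camera in place of 27, with 2 lists at an unadjusted p under 0.05 and 29 past fry. Of the genes at 2-fold or more, 1726 in all, limma's treat against 2-fold called 1023, a 1.5-fold limit gave 3073, a 4-fold limit 560, and reading the values as log10 would give 4731. Leaving out 1 array gave 3970 to 4674 genes, 1643 to 1857 genes at 2-fold or more, of which 1592 to 1702 were among the 1726, and 26 to 27 lists. Some counts of 4 or fewer list members past the test in 1 direction moved by over 1.5 times without 1 array, as given beside them. Of 128 recomputed list means, 126 kept their direction and side of the threshold. The other 2 were those of hepatic stellate, endothelial and biliary cells, whose mean of 0.55 was past the test with all arrays and not without array 2 (0.52) or array 3 (0.56). Its mean ranged from 0.52 to 0.57 over the 3 sets of 2 arrays. Of the genes named by the rule, 8 lost their call without at least 1 array: Slc10a1, Cd24a, Ly75, Foxm1, Lrat, Ppy, Myh4 and Psma1. Uty, not past the test, changed sign without array 2, ranging from -0.0074 to 0.0955 over the sets of 2 arrays. The causes of these changes were not tested. Keeping the zeros as values gave 4722 genes and 26 lists. The hepatic stellate, endothelial and biliary list did not pass there either (camera adjusted p = 0.062, mean 0.55). Genes with 1 measured probe gave 22 of 31 lists. Array 3's narrower range did not move the counts beyond these limits when arrays were scaled to the same spread (5016 genes, 1731 at 2-fold or more). Signal over background is unknown here, so a small ratio does not tell a dim probe from equal levels. Each log ratio already pairs the liver RNA with the spleen RNA on 1 array, so the test against 0 is a paired one. The 4 ways of giving signs to the 3 arrays are too few for a share under 0.05: the real one gave 5174 genes, as many as in 1 of 4, and the highest other gave 0, with 8 to 11 genes at an unadjusted limma p under 0.05.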

Other observations

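The family groups and tests in this part were chosen after the results were seen, except that on sequence records, whose prediction was written before its result.

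Gene families were formed from the letters before the first digit of the symbol alone, so members of a family need not share a function. Of 114 families with at least 10 measured genes, 10 lay toward liver and 7 toward spleen by camera with the preset correlation. With an estimated correlation none of these families passed (smallest adjusted p = 0.829). That setting rests on 2 residual degrees of freedom and passed none of the gene lists either. Oxidative phosphorylation, with 38 of 39 genes toward liver, had an adjusted p = 0.254 there. The estimated correlation therefore cannot decide whether the family calls hold. Of 40 Mrpl genes, named for the large subunit of the mitochondrial ribosome, 26 passed toward liver and 1 toward spleen (median 0.51, camera adjusted p = 3.02e-05), with Mrpl12 at 1.61 and Mrpl27 at 1.39. Of 20 Mrps genes, 13 passed toward liver and 1 toward spleen (median 0.43, adjusted p = 0.0115). Genes with the stem Pex passed toward liver in 10 of 11 cases (adjusted p = 0.00469), led by Pex11a at 2.83, and those with the stem Timm in 9 of 12 (adjusted p = 0.00506), led by Timm13 at 1.15. Genes with the stem Hsd passed toward liver in 10 of 16 cases (adjusted p = 0.00179), with Hsd3b3 at 4.15 and Hsd17b2 at 3.65.

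Toward spleen, immunoglobulin kappa variable segments (Igkv) passed in 10 of 11 cases, with a median of -1.36 (camera adjusted p = 0.00139). These segments resemble each other, and their probes are not known to be separate measurements. With an estimated correlation the family had an adjusted p = 0.909. Genes with the symbol stem Rbm passed toward spleen in 10 of 13 cases and toward liver in 2 (adjusted p = 0.0115), with Rbm3 at -1.64. Genes with the stem Lsm passed toward spleen in 8 of 10 cases (adjusted p = 0.0361), with Lsm3 at -1.89. Genes with the stem Ddx passed toward spleen in 9 of 18 cases and toward liver in 1 (adjusted p = 0.0296), with Ddx5 at -1.44. Of all 9803 genes, 2690 passed toward spleen and 2484 toward liver.

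Probes of the same gene often gave different ratios. Over 2649 pairs of probes, with Gapdh left out, the median absolute difference was 0.32 on the log2 scale, against 0.61 for random probes. In 100 of the 800 pairs with both probes past the test, the signs were opposite. The spread between arrays does not account for this, since the difference was 3.52 times that expected from it. Different sequence records do not account for it either, as pairs with the same accession differed as much as the others (ratio of medians 0.998, 95% bootstrap interval 0.864 to 1.17). A candidate explanation is that 1 probe of a pair gives no tissue-dependent signal. Where 1 probe was at least 1.5 from 0, the other lay within 0.3 of 0 in 110 pairs and beyond 0.3 on the opposite side in 26. That is a ratio of 4.23 (95% bootstrap interval 2.94 to 7) against 2.04 for random partners. This comparison cannot decide the question. Probes of a gene had correlated ratios (Pearson's r = 0.561 across pairs), and correlation alone leaves fewer partners on the opposite side. Probes of different splice forms or with weaker signal stay open as well.

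Gapdh shows the same kind of split. Of its 23 spots measured on all arrays, 16 averaged above 1, from 1.17 to 1.32, while 5 lay below 0, down to -0.60. The gene's mean of 0.84 lies between these groups.

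Of 14 skeletal muscle genes, 9 passed toward liver, and muscle tissue carried into the liver RNA could be a source. Over its 12 genes with 1 measured probe the list did not pass camera (adjusted p = 0.0584). Their mean of 0.87 was close to the 0.89 over all 14. With an estimated correlation the whole list did not pass either (adjusted p = 0.254). No gene list passed at that setting, so that result cannot decide whether the muscle call holds. Of 10 abundant muscle transcripts, 7 passed the test toward liver and 2 toward spleen, the latter creatine kinase (Ckm) at -0.40 and Myh4 at -0.68. Leaving out 1 array gave 6 or 7 toward liver, with 1 toward spleen without array 1 and 0 without array 2, where Ckm averaged -0.33 (adjusted p = 0.0681). The bounds for the test, at least 8 toward liver or at least 3 toward spleen, were set after the results were seen, and neither was met. They therefore decide nothing. Carry-over cannot be told apart from expression in liver itself, which was not tested, or from probes that detect related actin and myosin transcripts.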
